A study of Mus musculus with 8 samples.

How the data were processed

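Ribosome profiling libraries and matched input RNA libraries came from mouse embryonic fibroblasts (MEF) that express the SV40 T antigen. Cells stably transduced with an empty vector (EV) were compared with cells transduced with METTL1 and WDR4 together (OE). There were 4 groups of 2 libraries each: EV input, OE input, EV RPF and OE RPF, where RPF stands for ribosome-protected fragments. Per the labels' protocols, cells were treated with cycloheximide before lysis, ribosomal RNA was depleted, and both kinds of library were made with a commercial ribosome profiling kit. Groups and replicate numbers were taken from the description field of each sample. The labels describe stable clones and do not say whether the replicates came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical only. If each genotype is a single clone, a difference between clones apart from METTL1 and WDR4 would give the same p-values.

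The authors aligned reads to mouse build mm10 with Bowtie, per the submitters' processing notes. The Bowtie version, the counting program, its treatment of strand and of reads with several matches, and the annotation release are not given in the sources used here. The table holds 1 signal value per gene and library, deposited by the authors as size-factor-normalized reads. In each library every value was a whole multiple of the smallest value, within a tolerance of 1e-06, so whole reads were recovered for 100% of the values. The authors' factors equalled median-of-ratios size factors computed from the recovered reads. The authors also deposited a log2 fold change of translational efficiency (TE) and an unadjusted p-value for each gene. Both were checked against a DESeq2 Wald test of the interaction of genotype and library type on the recovered reads, and differed from it by at most 1.89e-14 (log2 fold change) and 1.48e-13 (p-value). The table has 9309 lines of values, of which 2 are blank, leaving 9307 genes, 9300 of them protein coding. Every listed gene has at least 1 read in each of the 8 libraries, so genes that lacked reads in 1 or more libraries are not analysed here.

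Gene identifiers were matched to GENCODE mouse release 21 (build mm10, also called GRCm38). Without the version suffix 9306 of them matched, and 84.4% matched with it. Symbols and coordinates (1-based) are those of that release. The 1 identifier without a match was kept in place of a symbol. For the longest annotated transcript of each gene, the share of 28-base subsequences found in no other annotated gene was computed. Its median was 99.8% over all genes. Exon overlap with other genes on either strand was computed for 245 named genes, of which 19 shared at least 20% of their exon bases with another gene.

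The design was fixed before the data were examined, with a branch for counts and a branch for normalized values. Since the table holds normalized values, the branch for normalized values was used. A linear model was fitted with limma 3.58.1 in R 4.3.3 to log2(value + 1) of all 8 libraries, with a mean-variance trend, a minimum mean value of 1 and no covariate. That minimum removed no gene. The fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The 3 contrasts were OE input against EV input (mRNA), OE RPF against EV RPF (RPF), and the RPF change minus the mRNA change (TE). P-values were two-sided and adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. Genes were named by a rule: among genes past the threshold, with a mean value of at least 5 and with both OE libraries beyond both EV libraries, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 6 genes passed, the 6 highest and the 6 lowest by fold change among genes with an unadjusted p under 0.01 were named as not past the threshold. Mettl1, Wdr4 and Hmga2 were named in every comparison, and up to 4 members per list with the smallest p. Symbols that begin with Gm and digits or end in Rik were counted and not named, and some genes that meet these rules are not reported here. Hmga2 was remembered from the study and is not independent evidence. Spp1, Gapdh, Actg1 and the genes compared between RPF and input within the EV cells were chosen after their values were seen.

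Tests of gene lists used camera from limma with a preset correlation of 0.01, adjusted over all tested lists and 3 comparisons, and repeated with an estimated correlation. A second list test from limma, fry, was fixed beforehand to stand beside camera and was adjusted in the same way. The count adjusted over the list alone applied the Benjamini-Hochberg method to the members of the list. There were 28 lists: the METTL1 complex, cytosolic ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, tRNA modification enzymes, mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, G1/S and DNA replication, G2/M and mitosis, centrosome, spindle and DNA damage kinases, replication-dependent histones, ATF4 and amino acid response, endoplasmic reticulum (ER) unfolded protein response, p53 targets, extracellular matrix and mesenchymal genes, type I interferon response, cholesterol biosynthesis, glycolysis and hypoxia, immediate-early and YAP/SRF targets, proteasome and chaperones, chromatin regulators, and markers of macrophages and leukocytes, epithelium, endothelium, muscle, adipocytes and neural cells. Lists with fewer than 5 measured members were counted and not tested. Not every member of a list is among the listed genes. Measured were 7 of 13 mitochondrially encoded mRNAs, 54 of 79 cytosolic ribosomal proteins and 12 of 38 type I interferon genes. Results for these lists cover the measured members only.

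Codon use was taken from the longest coding sequence of 9282 genes. The frequency of each of 61 sense codons was set against the TE change with Spearman's rho across genes and 100000 permutations, adjusted over the 61 codons, with 10000 permutations for the alternatives. Genes are not independent replicates of each other.

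For single genes, alternatives fixed beforehand were upper-quartile normalization, a pseudocount of 0.1, a minimum mean value of 5, a stricter count filter, the replicate number as a block, a block within each genotype, the libraries of a comparison alone, and each library left out in turn. For the lists they were the estimated correlation, the replicate block and the stricter count filter. For AGA they were genes with at least 100 reads on average, coding GC content and coding length held constant, the replicate block, the RPF or mRNA change in place of TE, and each library left out in turn. Chosen after the data were seen were the other alternatives for the lists and AGA, trimmed mean of M values (TMM) normalization of the recovered reads, edgeR 4.0.16 quasi-likelihood, limma voom and DESeq2 1.42.0 tests on the recovered reads, and the lists restricted to members with at least 90% unique subsequences. On simulated data drawn from these libraries, with 200 changed genes among 9307, a 2-fold change was recovered for 31.3% of the changed genes for mRNA, 46.3% for RPF and 10.4% for TE. A 4-fold change was recovered for 69.7%, 71.2% and 50% of them. False calls among the unchanged genes numbered 14, 2 and 0. For mRNA the 14 stood beside 7, 21 and 46 recovered genes with 1.5-fold, 2-fold and 4-fold changes. For RPF the 2 stood beside 5, 31 and 47. The share of false calls for mRNA was thus above the threshold of 0.05, so the reported mRNA calls may hold more false ones than that threshold states. A simulated list of 50 members moved 1.25-fold was called by camera, and 0 of 20 unmoved lists were called. The simulated genes were drawn independently of each other, so this does not test false calls in lists whose members vary together. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the remaining steps.

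Reads in the listed genes ranged from 294367 to 371520 per input library and from 526699 to 864147 per RPF library. Confidence intervals of shares are 95% Wilson intervals. Ratios that rest on 1 to 3 reads in a group are given with an exact 95% interval from the pooled reads. Reads carry no molecular identifiers, so these intervals cover counting error only.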

Results

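Input RNA and ribosome-protected fragments (RPF) were sequenced from mouse embryonic fibroblasts, connective tissue cells taken from mouse embryos, that express the SV40 T antigen, a viral protein that keeps cells dividing. The cells carried either an empty vector (EV) or vectors for METTL1 and WDR4 (OE). METTL1 is a methyltransferase that modifies a guanosine in a subset of tRNAs, and WDR4 is its partner in the complex. RPF are the stretches of mRNA that ribosomes shield from nuclease, so their number per mRNA measures translation. Each of the 4 groups had 2 libraries. Reads in the listed genes numbered 365962 and 371520 in the EV input libraries and 294367 and 357305 in the OE input libraries. The EV RPF libraries held 707344 and 618526 reads, and the OE RPF libraries 864147 and 526699. The median gene had 15 to 19 reads in an input library and 23 to 38 in an RPF library. Values below are size-factor-normalized reads, and tests are limma tests with adjusted p-values unless another tool is named. The first principal component of the libraries (66.7% of the variance) separated input from RPF, and the second (9.25%) separated EV from OE in both kinds of library.

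The genes of the METTL1 complex were examined first in every library. Mettl1 (ENSMUSG00000006732.14, build mm10, chromosome 10, 127041414 to 127046365, plus strand) had input values of 16.69 and 14.01 in EV and of 33.72 and 15.98 in OE. Its RPF values were 25.7 and 25.6 in EV and 40.1 and 22.4 in OE. Wdr4 (ENSMUSG00000024037.12, chromosome 17, 31494322 to 31519980, minus strand) had input values of 16.7 and 26.8 in EV and of 24.1 and 42.6 in OE. Its RPF values were 15.2 and 15.1 in EV and 25.8 and 24.2 in OE, so that both OE RPF libraries lay above both EV RPF libraries. The mRNA log2 fold changes were 0.58 (SE 0.34, adjusted p = 0.482) for Mettl1 and 0.58 (SE 0.32, adjusted p = 0.454) for Wdr4. The RPF log2 fold changes were 0.22 (adjusted p = 0.881) and 0.69 (adjusted p = 0.454). Neither gene of the METTL1 complex passed the threshold in any comparison, over all genes or adjusted over the list alone. The labels do not say which species' sequence the vectors carry, and reads of a human sequence may not all be counted for the mouse gene, so whether these values measure the transgenes is not known. If the vectors carry mouse sequence, the values go against the overexpression that the labels state. The Mettl1 values rest on 11 to 21 input reads per library. Without the first OE RPF library the RPF change of Mettl1 was -0.185.

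The comparison of input libraries asks which mRNAs differ in amount between OE and EV cells. Igfbp4, an insulin-like growth factor binding protein (chromosome 11, 99041244 to 99054392), rose from 1.92 ± 0.915 to 22.4 ± 9.14 (SD, n = 2), a log2 fold change of 2.98 (SE 0.48, adjusted p = 5.86e-04). Esx1, an X-linked homeobox factor (chromosome X, 137115397 to 137122083), rose from 3.84 ± 0.0212 to 27.6 ± 0.467 (SD, n = 2), a log2 fold change of 2.57 (SE 0.39, adjusted p = 3.29e-04). A single read counts as 1.28 and 1.27 in the EV input libraries, so the EV mean of Esx1 rests on few reads. Its small SD does not measure counting error. Tes, a LIM domain protein of focal adhesions (chromosome 6, 17065149 to 17105828), rose from 37.7 ± 9.74 to 131 ± 15.6 (SD, n = 2), a log2 fold change of 1.79 (SE 0.20, adjusted p = 2.48e-06). Igsf10, an immunoglobulin superfamily member (chromosome 3, 59316735 to 59344394), fell from 19.8 ± 8.25 to 1.47 ± 0.194 (SD, n = 2), a log2 fold change of -3.02 (SE 0.50, adjusted p = 6.55e-04). Amot, the cell junction protein angiomotin that binds YAP, fell from 41.6 ± 1.13 to 12.3 ± 1.47 (SD, n = 2), a log2 fold change of -1.68 (SE 0.25, adjusted p = 3.29e-04). In all, 140 of 9307 genes passed the threshold, 94 higher and 46 lower in OE.

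Among the other named mRNAs that rose were Pkp1 (plakophilin, 2.37), Plau (urokinase, 2.33), Itgb7 (2.16), Ubash3b (2.04), Nsg1 (2.04), Atp2b4 (1.89), Dclk1 (1.86) and Timm10 (1.81), all as log2 fold changes. Those that fell were Sema3f (a semaphorin, -2.22), Polm (DNA polymerase mu, -2.19), Zbtb43 (-2.10), Hacd4 (-2.08), Gchfr (-2.07), Rcan2 (-1.99), Mbnl2 (a splicing regulator, -1.44), Lrba (-1.42), Gabarapl1 (an autophagy factor, -1.32) and Ap3b1 (an adaptor subunit of vesicle transport, -1.29). Several of these rest on few reads. Low EV input means were also those of Itgb7 (2.56 ± 0.0141) and Nsg1 (5.10 ± 5.40, SD, n = 2). The pooled input reads of Igfbp4 were 3 in EV and 30 in OE, a ratio of 11.4 with an exact 95% interval of 3.54 to 58.3. Those of Igsf10 were 31 in EV and 2 in OE, a ratio of 13.6 (3.46 to 117). The corresponding ratios were 5.69 (1.61 to 30.7) for Ubash3b and 4.93 (1.36 to 27.0) for Dclk1, OE over EV. They were 6.44 (1.94 to 33.6) for Sema3f, 7.03 (1.65 to 63.0) for Polm, 6.59 (1.53 to 59.4) for Zbtb43, 5.56 (1.64 to 29.4) for Gchfr and 5.27 (1.54 to 27.9) for Rcan2, EV over OE. Exons of Gabarapl1 shared 28.3% of their bases with an antisense gene, so its value is uncertain. Spp1, which encodes the secreted protein osteopontin and was chosen after its values were seen, rose by 1.19 (SE 0.08, adjusted p = 1.83e-10).

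At an unadjusted p under 0.05 there were 1245 genes, and the EV and OE input libraries did not overlap for 40.6% of genes, where chance gives 33.3%. The number of calls was 57 with edgeR, 49 with limma voom and 15 with DESeq2 on the recovered reads, and 62 with the 4 input libraries alone. It was 66 (52 higher, 14 lower) without the first EV input library and 50 (40 higher, 10 lower) without the second. Without the first OE input library it was 81 (45 higher, 36 lower), and without the second it was 156 (67 higher, 89 lower), so that the more frequent direction depended on 1 library. Of 50 mRNAs past the threshold that the rules for named genes and list members selected, 21, 20, 29 and 28 remained so without the first or second EV input library or the first or second OE input library, all with the same sign.

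**Figure D1:**
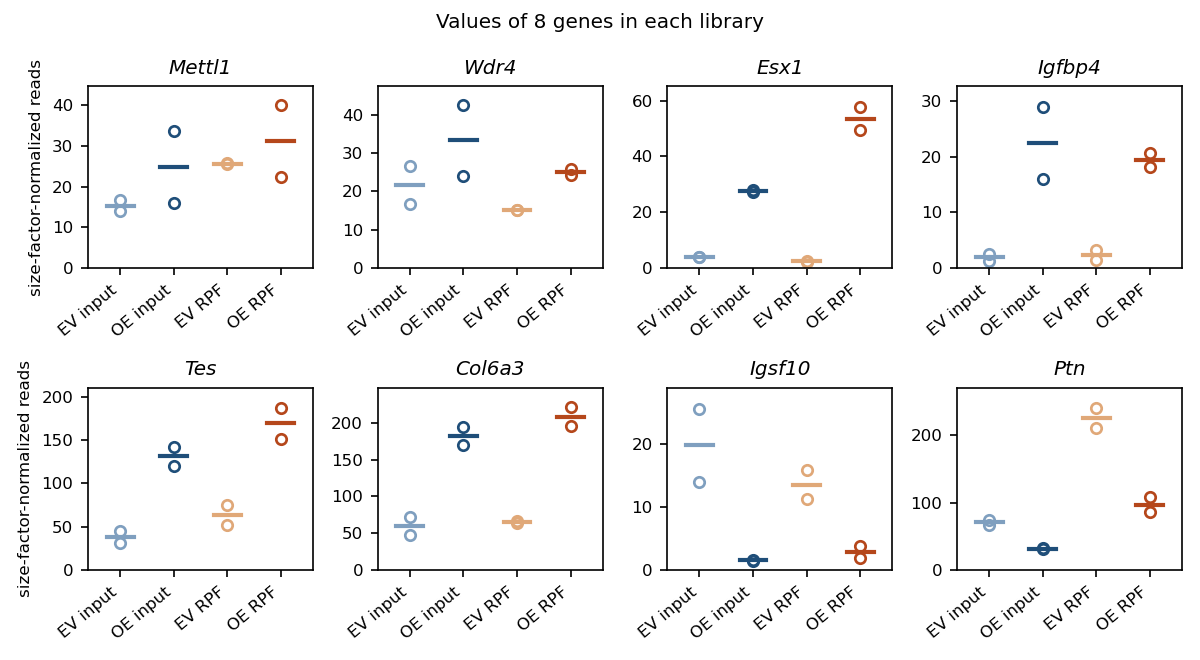
Size-factor-normalized reads of 8 genes in each library, with open circles for the 2 libraries of a group and a line for their mean, in EV and OE input and RPF libraries. Esx1, Igfbp4, Tes and Col6a3 were higher and Igsf10 and Ptn lower in OE in both kinds of library, while the EV and OE input values of Mettl1 and Wdr4 overlapped.

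Among the fixed gene lists, extracellular matrix and mesenchymal mRNAs were higher in OE (camera, adjusted p = 3.31e-11), with 10 of 45 measured members higher and 0 lower. Adjusted over the list alone, 16 were higher and 2 lower. The collagen chains Col6a3 (1.63), Col4a1 (1.12) and Col1a1 (0.46) and the matrix protease Mmp3 (1.62) rose. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher (adjusted p = 8.00e-07), with 6 of 23 passing and 9 passing when adjusted over the list alone. Nars rose by 0.81, Cars by 0.95, Tars by 0.58 and Gars by 0.51. Targets of ATF4 and the amino acid response were also higher (adjusted p = 1.08e-06), with 4 of 30 passing and 7 passing when adjusted over the list alone. Those 4 were Asns (asparagine synthetase, 0.74), the glutamine transporter Slc1a5 (1.74), Gpt2 (1.49) and Psat1 (0.48). These 3 calls held with an estimated correlation, with adjusted p = 0.0212, 0.045 and 0.0368. They also held with fry, with adjusted p = 0.0103, 0.02245 and 0.0244.

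The other 7 list calls in the input libraries were lost with an estimated correlation. With fry the adjusted p was 0.0312 for immediate-early targets, 0.0317 for the ER and G2/M lists and 0.0743 for the proteasome list. For the centrosome list and histones fry gave an adjusted p of 0.307, and for chromatin regulators 0.135. Immediate-early and YAP/SRF targets were higher (camera, adjusted p = 3.87e-06; adjusted p = 0.0681 with an estimated correlation), with Fosl1 (0.89), a member of the AP-1 family whose exons overlap another gene over 57.2% of their bases, as 1 of 30 passing and 7 passing when adjusted over the list alone. ER unfolded protein response genes were higher with 0 of 24 passing and 2 adjusted over the list alone (camera, adjusted p = 0.003; adjusted p = 0.131 with an estimated correlation), with Hspa5 at 0.35 and Xbp1 at 1.19. Proteasome and chaperone genes were higher with 0 of 49 passing and 2 adjusted over the list alone (camera, adjusted p = 0.0283; adjusted p = 0.181 with an estimated correlation). G2/M and mitosis genes were lower (camera, adjusted p = 1.35e-04; adjusted p = 0.137 with an estimated correlation). The condensin subunit Ncapd2 (-0.54) and the mitotic kinase Cdk1 (-0.49) fell, as 2 of 52, with 5 lower when adjusted over the list alone. Centrosome, spindle and DNA damage kinase genes were lower with 0 of 37 passing and, adjusted over the list alone, 1 higher and 5 lower (camera, adjusted p = 0.0242; adjusted p = 0.451 with an estimated correlation). Replication-dependent histones were lower (camera, adjusted p = 0.0251; adjusted p = 0.362 with an estimated correlation), although Hist2h4 rose by 0.51 and Hist1h2ad fell by 1.09 on the log2 scale among 46 members, over all genes and when adjusted over the list alone. Histone genes share sequence, and only 32% of the subsequences of Hist1h2ad were unique, so its value is uncertain. Chromatin regulators were lower (camera, adjusted p = 0.0335; adjusted p = 0.297 with an estimated correlation), with Smarcc2 (-0.68) as the 1 of 50 that fell, over all genes and over the list alone.

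Some of these list calls were also lost without 1 library. Without the first EV input library the adjusted p was 0.266 for the centrosome list, 0.119 for chromatin regulators and 0.161 for the proteasome list, and without the second it was 0.053 for chromatin regulators and 0.127 for histones. Without the first OE input library it was 0.191 for the centrosome list and for chromatin regulators, and without the second it was 0.0787 for the ER list, 0.279 for the proteasome list and 0.519 for histones.

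Members of lists without a list call also changed. In the G1/S and DNA replication list Ccnd1 (cyclin D1, 0.80, uncertain since 23.4% of its exon bases overlap another gene) and the helicase subunit Mcm6 (0.49) rose, and the list of 52 had a median of -0.04, a mean of 0.02 and a camera direction of lower (adjusted p = 0.894). Adjusted over the list alone, 3 were higher and 2 lower. Eef2 (-0.44) and Eif4a2 (-0.69) fell among 38 translation factors (adjusted p = 0.899; 2 higher and 2 lower over the list alone). Atp5b fell by 0.40 on the log2 scale and Ndufa5 rose by 0.81 among 70 nuclear-encoded oxidative phosphorylation genes (adjusted p = 0.858; 3 higher and 4 lower over the list alone). Ldha (0.53), which shares sequence with copies, was the 1 of 25 glycolysis and hypoxia genes that rose (adjusted p = 0.377), also over the list alone. The list of 38 tRNA modification enzymes had no list call (adjusted p = 0.0822). No member passed, over all genes or over the list alone, among 54 cytosolic ribosomal proteins (adjusted p = 0.506), 74 mitochondrial ribosomal proteins (0.646), 7 mitochondrially encoded mRNAs (0.195), 22 p53 targets (0.761), 12 type I interferon genes (0.489) and 24 cholesterol biosynthesis genes (0.0984). Of markers of other cell types, 2 of adipocytes, 1 of endothelium, 3 of epithelium, 2 of macrophages and leukocytes and 4 of neural cells were measured, and 0 of muscle. None of them passed for mRNA over all genes, and 1 neural marker passed over the list alone. Hmga2, a chromatin protein gene remembered from the study (chromosome 10, 120361275 to 120476469), had an mRNA change of 0.18 (SE 0.23, adjusted p = 0.784).

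The comparison of RPF libraries asks which mRNAs carried more or fewer ribosomes in OE cells. Esx1 rose from 2.45 ± 0.268 to 53.5 ± 5.82 (SD, n = 2), a log2 fold change of 3.98 (SE 0.39, adjusted p = 3.04e-07). Col6a3, a chain of type VI collagen (chromosome 1, 90765923 to 90843971), rose from 65.5 ± 2.16 to 209 ± 17.9 (SD, n = 2), a log2 fold change of 1.66 (SE 0.17, adjusted p = 5.46e-07). Ptn, the secreted growth factor pleiotrophin (chromosome 6, 36714929 to 36810220), fell from 226 ± 20.7 to 96.9 ± 15.1 (SD, n = 2), a log2 fold change of -1.22 (SE 0.17, adjusted p = 1.28e-04). Igsf10 fell by 1.97 on the log2 scale (SE 0.50, adjusted p = 0.0493). In all, 89 genes passed, 67 higher and 22 lower.

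The other named genes with more RPF were Igfbp4 (2.63), the sialyltransferase St3gal1 (2.11), Ptprn (1.81), Pkp1 (1.71), Mdfic (1.65), the receptor Notch1 (1.61), the alanine aminotransferase Gpt2 (1.58), Rpl13a (1.52) and the growth factor Ereg (1.48). Rpl13a has pseudogene copies, 41.7% of its subsequences were unique and 35.4% of its exon bases overlap other genes, so its value is uncertain. Those with fewer RPF were Arl6ip1 (-1.52), Ank3 (ankyrin-G, -1.23), Esyt1 (-1.05), the myosin light chain Myl6 (-1.02), the caveolar protein Cavin2 (-0.98), Ttyh2 (-0.96), Map1a (-0.71), the sphingosine phosphate lyase Sgpl1 (-0.70), Reep5 (-0.67) and the actin regulator Coro1b (-0.66). Spp1 rose by 1.09.

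At an unadjusted p under 0.05 there were 953 genes, and the EV and OE RPF libraries did not overlap for 44.1% of genes, where chance gives 33.3%. The number of calls was 301 with edgeR, 319 with limma voom and 25 with DESeq2 on the recovered reads, and 157 with the 4 RPF libraries alone. It was 26 (25 higher, 1 lower) without the first EV RPF library and 16 (14 higher, 2 lower) without the second, so that almost no lower calls were left. It was 47 (30 higher, 17 lower) without the first OE RPF library and 70 (49 higher, 21 lower) without the second. Of 44 genes past the threshold for RPF that the same rules selected, 13, 9, 19 and 24 remained so without the first or second EV RPF library or the first or second OE RPF library, all with the same sign.

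RPF of mitochondrially encoded mRNAs, which encode subunits of the respiratory chain, were higher (camera, adjusted p = 5.54e-17), with 6 of 7 measured members higher, 7 when adjusted over the list alone, and a median of 0.85. The members mt-Nd1 (1.32, chromosome M, 2751 to 3707), mt-Nd2 (1.06), mt-Nd5 (0.76) and mt-Co1 (0.75) rose. The mean of mt-Nd1 went from 6.87 to 17.8 and that of mt-Co1 from 28.9 to 49.4. Of mt-Co1, 33.3% of the subsequences were unique, so its value is uncertain. These 7 mRNAs took 0.0253% (Wilson interval 0.0219% to 0.0293%) and 0.0192% (0.0161% to 0.023%) of the EV RPF reads and 0.0433% (0.0391% to 0.0479%) and 0.0366% (0.0318% to 0.0422%) of the OE RPF reads, against 2.62% to 2.97% of the input reads. Single members passed in 4 cases with edgeR, 3 with limma voom, 0 with DESeq2 and 0 with the 4 RPF libraries alone. The list stayed past the threshold with those 4 libraries, tested only with the preset correlation.

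Cytosolic ribosomal proteins were higher for RPF (camera, adjusted p = 9.02e-09), with 6 of 54 higher and, adjusted over the list alone, 14 higher and 1 lower. The median was 0.27. Rps15a rose 2.39-fold, and Rps3a1 and Rps27a rose by 0.83 and 1.68 on the log2 scale. The pooled reads of Rps27a were 3 in EV and 17 in OE, a ratio of 5.49 (exact 95% interval 1.59 to 29.2), and sequence shared with copies makes Rps3a1 and Rps27a uncertain. ATF4 and amino acid response genes were higher (adjusted p = 3.31e-11), with Asns (0.78) and Gpt2 (1.58) as 2 of 30 and 12 when adjusted over the list alone. Extracellular matrix and mesenchymal genes were higher (adjusted p = 9.02e-09), with 7 of 45 and 13 when adjusted over the list alone, among them the protease inhibitor Timp1 (0.92), tenascin Tnc (0.98) and Col1a1 (0.39). Aminoacyl-tRNA synthetases were higher (adjusted p = 8.00e-07), with Eprs (0.53) as 1 of 23 and 6 when adjusted over the list alone. These 5 list calls held with an estimated correlation, at adjusted p = 0.0212 for the mitochondrially encoded, ribosomal protein, ATF4 and matrix lists and 0.045 for the synthetases. Without 1 RPF library at a time the ribosomal proteins that passed singly numbered 3, 1, 1 and 9.

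The other 6 list calls for RPF were lost with an estimated correlation. With fry the adjusted p was 0.02245 for translation factors, 0.0244 for the G2/M list and 0.0402 for the G1/S list. For the ER list fry gave an adjusted p of 0.0681, for immediate-early targets 0.077 and for the centrosome list 0.32. Translation factors were higher (camera, adjusted p = 3.77e-06; adjusted p = 0.0534 with an estimated correlation), with Eef1b2 (0.48) as 1 of 38 and 5 when adjusted over the list alone. Immediate-early and YAP/SRF targets were higher (camera, adjusted p = 0.003; adjusted p = 0.154 with an estimated correlation), with Myc (0.77) as 1 of 30 and 5 over the list alone. ER unfolded protein response genes were higher with 0 of 24 passing, also over the list alone (camera, adjusted p = 0.0219; adjusted p = 0.181 with an estimated correlation). G2/M and mitosis genes were lower (camera, adjusted p = 5.98e-07; adjusted p = 0.0723 with an estimated correlation), with Ncapd2 (-0.59) and Cdk1 (-0.54) as 2 of 52 and 8 over the list alone. G1/S and DNA replication genes were lower with 0 of 52 passing, also over the list alone (camera, adjusted p = 0.0224; adjusted p = 0.171 with an estimated correlation). Centrosome, spindle and DNA damage kinase genes were lower with 0 of 37 passing and 1 over the list alone (camera, adjusted p = 0.0144; adjusted p = 0.433 with an estimated correlation). Without the second OE RPF library the adjusted p was 0.56 for the centrosome list, 0.0635 for the ER and immediate-early lists and 0.082 for the G1/S list. Without the first EV RPF library it was 0.104 for the G1/S list, and without the second it was 0.0552 for the centrosome list and 0.0936 for the ER list.

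Outside these lists, Eno1 (0.74, with 22% unique subsequences and so uncertain) rose in the glycolysis list (camera, adjusted p = 0.169). In that list 3 were higher and 1 lower over the list alone. Atp5b (-0.49) fell in the oxidative phosphorylation list (camera, adjusted p = 0.453). Hist1h4f (-0.65, 45% unique and so uncertain) fell among histones (camera, adjusted p = 0.485), of which 6 were higher and 7 lower over the list alone. Among neural markers Ncam1 (0.70), which fibroblasts can also express, rose, and over the list alone 2 passed. The adipocyte, endothelial, epithelial and macrophage markers had 0 passing over all genes, and 1 epithelial marker passed over the list alone. Camera gave adjusted p = 0.269 for chromatin regulators, 0.195 for cholesterol biosynthesis, 0.39 for mitochondrial ribosomal proteins, 0.11 for p53 targets, 0.561 for the proteasome list, 0.926 for tRNA modification enzymes and 0.0996 for type I interferon genes. The RPF change of Hmga2 was -0.20 (SE 0.23, adjusted p = 0.842).

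Changes of input and RPF were compared gene by gene. Of the genes past the threshold, 40 were shared, 32 higher and 8 lower in both, where independent sets of calls would share 0.677 and 0.109. The sets are not independent, since the fit gives a gene the same SE in both comparisons, so those numbers are no valid chance level. Esx1, Igfbp4, Pkp1, Col6a3, Gpt2, Asns and Spp1 were among the 32 and Igsf10, Ncapd2, Cdk1 and Atp5b among the 8. Across all genes, which are not independent replicates, the log2 fold changes had a Pearson's r of 0.298 and a Spearman's rho of 0.28. Of 140 mRNA calls, 133 had an RPF change of the same sign.

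**Figure D2:**
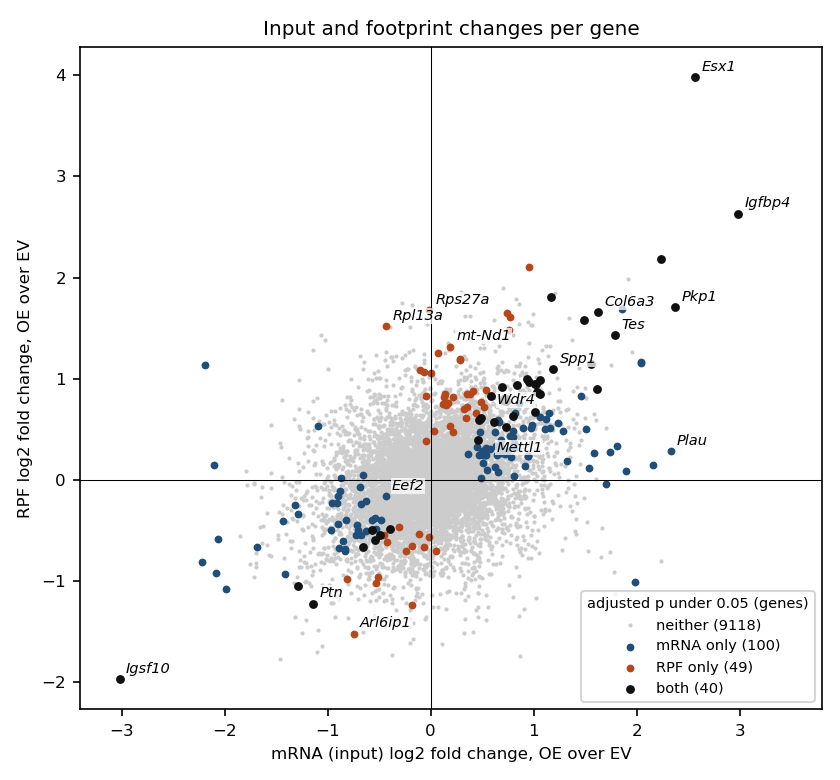
Log2 fold change (OE over EV) of input mRNA on the horizontal axis against that of RPF on the vertical axis, 1 point per gene, coloured by the comparison in which the gene passed the adjusted threshold. The 40 genes past it in both lie in the quadrants where the 2 changes share a sign, with Esx1 highest and Igsf10 lowest among the labelled ones.

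Translational efficiency, the RPF change beyond the input change, is the question the series is built around. With limma 0 of 9307 genes passed, with 508 at an unadjusted p under 0.05 and a smallest adjusted p of 0.331. The count was 1 with edgeR, 0 with limma voom and 0 with DESeq2, which gave 70 genes at an unadjusted p under 0.05. In the authors' deposited table the number of genes with a p under 0.05 was 70, 41 with higher and 29 with lower TE, and the smallest p of 0.00125 became 0.9997 after Benjamini-Hochberg adjustment. With RPF and input libraries paired by replicate number, the TE values of EV and OE did not overlap for 33.5% of genes, where chance gives 33.3%. On simulated data this test recovered 10.4% of 2-fold and 50% of 4-fold changes, so that most 2-fold changes of single genes were missed there. The count was 2 without the first OE input library, 2 without the first EV RPF library and 5 without the second OE RPF library. A replicate block within genotype gave 7, 6 higher and 1 lower.

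The largest TE changes among genes with an unadjusted p under 0.01, none past the threshold, were those of Polm (3.32, SE 0.74, adjusted p = 0.395), Mcrip2 (2.50), Slc30a1 (2.42), Slc35g1 (2.41), Itpkc (2.27) and Zbtb43 (2.25) upward. Downward they were those of Hist1h2af (-3.04, adjusted p = 0.899), Fbxl12 (-2.99), Srr (-2.92), Ndufb4 (-2.69), Tyw3 (-2.61) and Ten1 (-2.46). The OE input values of Hist1h2af were 27.3 and 1326, so that 1 library decided its value, and 13.2% of its subsequences were unique. The other 11 genes had group means of at most 18.9, and 7 of them had a group with 2 or 3 pooled reads in input or RPF. Exons of Fbxl12 (37.1% of their bases), Srr (30%) and Itpkc (24.1%) overlap other genes, so these values are uncertain as well. Besides Polm and Zbtb43, the input ratios were 2.63 (exact 95% interval 0.658 to 15.1) for Mcrip2, 3.07 (0.585 to 30.3) for Slc30a1 and 3.51 (0.701 to 34.0) for Itpkc, EV over OE, and 6.26 (1.37 to 58.1) for Fbxl12, OE over EV. The RPF ratio of Ndufb4 was 2.75 (0.66 to 16.1), EV over OE. The TE change of Hmga2 was -0.39 (SE 0.32, adjusted p = 0.936), and in the authors' deposited table it was -0.39 with a p of 0.408. Those of Mettl1 and Wdr4 were -0.36 (adjusted p = 0.972) and 0.11 (adjusted p = 0.994).

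As groups, cytosolic ribosomal protein mRNAs had higher TE (camera, adjusted p = 9.02e-09). Of 54 measured members (79 in the list) 41 had a change above 0, with a median of 0.27, 0 passing over all genes and 6 higher when adjusted over the list alone. Rpl13a (1.95), Rps27a (1.69) and Rpl32 (0.71) had the smallest p, and all share sequence with copies. Mitochondrially encoded mRNAs had higher TE (adjusted p = 3.31e-11), with 7 of 7 measured members (13 in the list) above 0 and a median of 0.67. Of these members 0 passed over all genes and 5 over the list alone, among them mt-Nd1 (1.13). Both calls held with an estimated correlation (adjusted p = 0.0212 and 0.0368). With fry the ribosomal protein call held (adjusted p = 0.0195), and the mitochondrially encoded call did not (adjusted p = 0.0734). For the 3 further TE lists called by camera, fry gave an adjusted p of 0.0317 (translation factors), 0.104 (proteasome and chaperones) and 0.168 (type I interferon). Translation factors had higher TE (camera, adjusted p = 1.06e-04; adjusted p = 0.0723 with an estimated correlation), with 0 of 38 passing, also over the list alone, and Eif3f at 0.74. Proteasome and chaperone genes had lower TE (camera, adjusted p = 0.00742; adjusted p = 0.137 with an estimated correlation), as had 12 type I interferon genes (camera, adjusted p = 0.0308; adjusted p = 0.181 with an estimated correlation), with 0 members passing in either list, also over the list alone. The proteasome call was lost without the first EV input library (adjusted p = 0.0603) and the second OE input library (0.136). The interferon call was lost without those libraries (0.245 and 0.194), without the second EV RPF library (0.0866) and without the second OE RPF library (0.0785).

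No other list was called for TE, and no other member of a tested list passed over all genes. Camera gave adjusted p = 0.579 for synthetases, 0.334 for ATF4 targets, 0.942 for the centrosome list, 0.7 for cholesterol biosynthesis, 0.377 for chromatin regulators and for oxidative phosphorylation, 0.506 for the ER list and 0.195 for matrix genes. It gave 0.0752 for G1/S, 0.536 for G2/M, 0.785 for glycolysis and hypoxia, 0.151 for immediate-early targets, 0.773 for mitochondrial ribosomal proteins, 0.337 for p53 targets, 0.23 for histones and 0.123 for tRNA modification enzymes. The camera direction was higher while the median was below 0 for glycolysis (-0.03) and the mean was below 0 for the centrosome list (-0.01). Over the lists alone 2 histones and 1 macrophage marker passed.

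**Figure D3:**
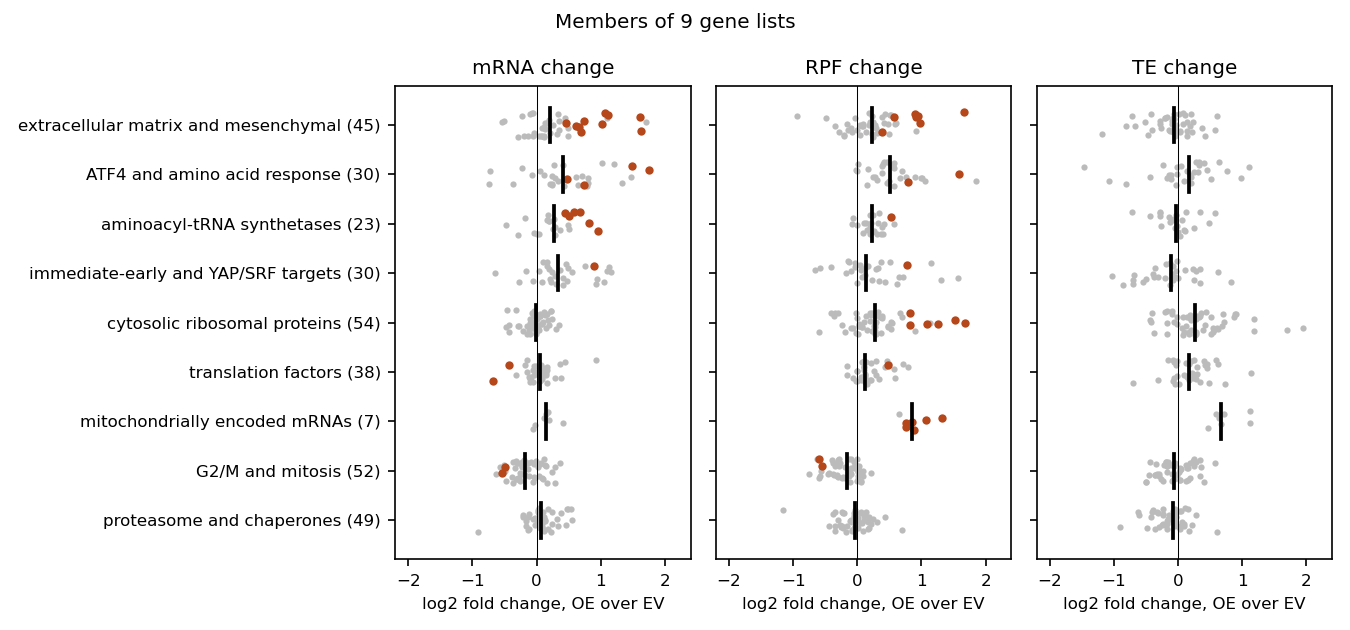
Log2 fold changes (OE over EV) of the members of 9 gene lists for mRNA, RPF and TE, with 1 point per gene, a black bar at the median of the list, orange points for genes past the adjusted threshold and the number of members in parentheses. RPF and TE of the 7 measured mitochondrially encoded mRNAs lay above 0 for every member, and no point of the TE panel is orange.

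Codon use was examined because METTL1 modifies the arginine tRNA that reads AGA. Across 9282 genes, the frequency of AGA in the coding sequence and the TE change had a Spearman's rho of 0.0443 (permutation p = 3e-05, adjusted over 61 codons 1.22e-04). AGA ranked 10 among the 61 codons, of which 39 passed, 22 with a rho above 0 and 17 below. The highest rho was 0.0679 for AAT and the lowest -0.0657 for GAG. Between the replicates of 1 genotype, with RPF and input libraries paired by number, the largest codon rho in size was greater, at 0.0827 for EV and 0.18 for OE. Of 30 codons that end in A or T, 27 had a rho above 0, and of 31 that end in G or C, 30 had a rho below 0. With coding GC content and coding length held constant, the rho of AGA was 0.00648 (permutation p = 0.539). The tenth of genes richest in AGA (929 genes) had a median TE change of 0.0471 against -0.0112 for the others (camera, p = 0.238; p = 0.391 with an estimated correlation). The rho was -0.00235 without the first OE input library, -0.0161 without the first OE RPF library, 0.0234 without the second EV input library, 0.0811 without the second OE input library and 0.0915 without the second OE RPF library.

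**Figure D4:**
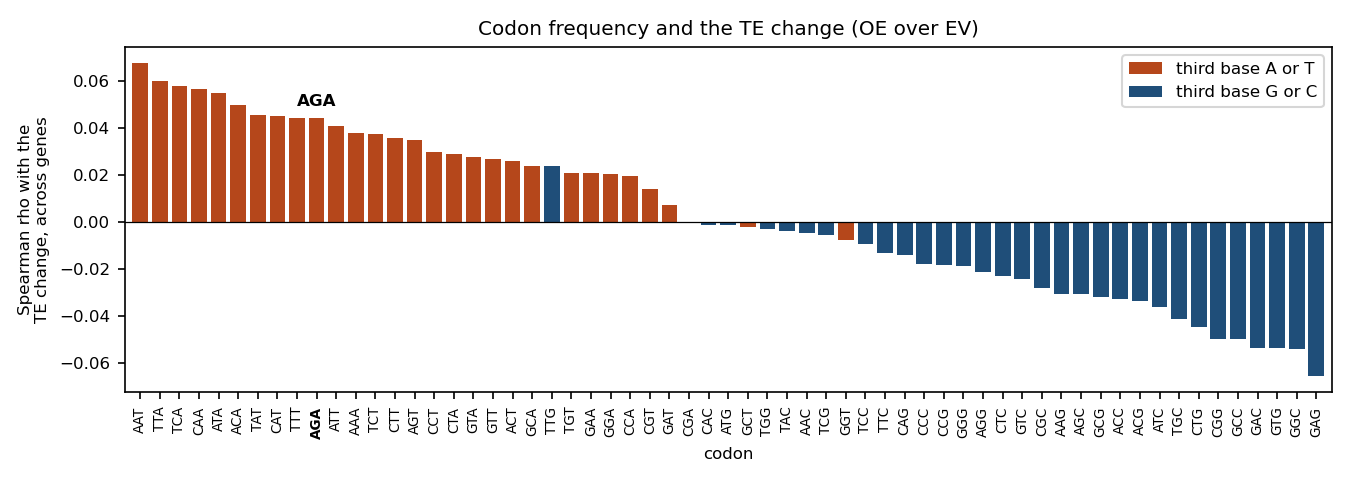
Spearman's rho across genes between the frequency of each of 61 sense codons and the TE change (OE over EV), ordered by rho and coloured by the third base of the codon. AGA stands at 0.0443, behind 9 other codons, and codons that end in A or T make up most of those above 0.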

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

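Tests chosen after the data were seen were those with edgeR, limma voom and DESeq2 on the recovered reads, TMM normalization, every alternative for the lists except the estimated correlation, the replicate block and the stricter count filter, and for AGA the other normalization, pseudocount, filters and replicate block within genotype. The numbers of calls for mRNA, RPF and TE were 140, 89 and 0 and stayed within 1.5 times these under TMM, upper-quartile normalization, a pseudocount of 0.1, a minimum mean of 5 and the stricter count filter. A minimum mean of 1 removed no gene, so testing without a filter equals the reported test, and median-of-ratios size factors equal the deposited ones. Other tests gave 57, 301 and 1 (edgeR), 49, 319 and 0 (limma voom) and 15, 25 and 0 (DESeq2), with 56, 85 and 0 (edgeR) shared with the reported calls. DESeq2 gave no adjusted p for 3609 genes (mRNA) and 5774 genes (RPF). The libraries of a comparison alone gave 62 (mRNA) and 157 (RPF), of which 61 and 77 were shared. The reported fit gives both changes of a gene the same SE (median 0.321). The SD of the log2 difference between replicates was 0.56 (EV) and 0.593 (OE) in input and 0.443 and 0.506 in RPF. The shared SE may thus raise the mRNA calls and lower the RPF calls, so 140 against 89 does not rank mRNA above RPF. Whether this accounts for all the differing counts was not tested. With 1 library left out, which leaves an arm of 1 library assumed to vary like the other groups, the counts ranged from 50 to 156 (mRNA), 16 to 70 (RPF) and 0 to 5 (TE), with fewer libraries in the fit. No named gene or list past a threshold changed direction under any alternative run.

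Deviations of libraries with the same replicate number correlated at -0.0194 to 0.0274, so no pairing by number was seen. This does not exclude pairing, since replicates differed by little beyond counting error in most groups. The chi-square of the reads between replicates, per degree of freedom, was 1.09 (EV input), 1.20 (OE input), 1.07 (EV RPF) and 1.73 (OE RPF). With the number as a replicate block the calls were 137 (mRNA), 88 (RPF) and 0 (TE), and no named gene or list call changed. A replicate block within genotype gave 7 TE calls, 6 higher and 1 lower.

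Lists called for mRNA, RPF and TE numbered 10, 11 and 5. With an estimated correlation 3, 5 and 2 remained. Fry kept all of these except that of the mitochondrially encoded mRNAs for TE (adjusted p = 0.0734). With 1 library left out the numbers ranged from 7 to 10, 7 to 11 and 3 to 6. Under the other settings the numbers stayed within 1.5 times the reported ones, but a call was lost in 7 cases. For RPF the stricter count filter ended those of the ER list (adjusted p = 0.0759) and the immediate-early list (0.093), and limma voom that of the centrosome list (0.0506). A minimum mean of 5 ended that of chromatin regulators for mRNA (0.0563). Members with at least 90% unique subsequences did not pass for the proteasome list for mRNA (0.0509) and for the ER (0.0509) and G1/S (0.052) lists for RPF. That restriction left too few members to test histones and the mitochondrially encoded mRNAs, and the stricter filter too few interferon genes.

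The rho of AGA frequency (0.0443) kept its sign except with the mRNA change in place of TE (-0.0254) and without a first OE library (-0.00235 for input, -0.0161 for RPF), and ranged from -0.0161 to 0.0915 with 1 library left out. It was 0.0443 with the replicate block and 0.0288 with the RPF change in place of TE. Over the 1134 genes with at least 100 reads on average the rho was 0.0627 (permutation p = 0.0341), without GC content or length held constant. Given coding GC content and coding length, over all genes, the rho fell to 0.00648. Of values that were not past a threshold, the mRNA change of Hmga2 (0.18) was 0.398 without the first EV input library, -0.0302 without the second EV input library and -0.0254 without the first OE input library. The RPF change of Mettl1 was -0.185 without the first and 0.623 without the second OE RPF library. Its TE change (-0.36) was 0.16 without the first OE input library, -0.872 without the second, and 0.048 without the second OE RPF library. The TE change of Wdr4 (0.11) was -0.212 without the second EV input library, -0.286 without the first OE input library and 0.511 without the second. The cause was not tested.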

Other observations

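The tests chosen after the result was seen were the comparison of RPF with input within the EV cells, the rank of AGA among the codons, and the 3 tests of the mitochondrially encoded mRNAs. The restriction of lists to members with unique sequence was added once the data had been seen, with its prediction written before its result. Within the EV cells, RPF and input values of a gene were compared with limma, and of 9307 genes 1726 passed the adjusted threshold of 0.05 with higher and 1779 with lower RPF than input values. The members counted below as higher or lower are those past this threshold. Replication-dependent histones, the core proteins of chromatin made in S phase, had a median log2 ratio of 1.40, with 40 of 46 higher (camera, adjusted p = 2.16e-26; adjusted p = 0.0109 with an estimated correlation). Hist1h2bj, for example, had a log2 ratio of 2.77, from 51.8 ± 1.19 to 362 ± 62.0 (SD, n = 2). Nuclear-encoded oxidative phosphorylation genes had a median of 0.87, with 54 of 70 higher, and Cox8a stood at 2.29. Extracellular matrix and mesenchymal genes had a median of 0.70 (33 of 45 higher), the proteasome and chaperone list 0.69 (33 of 49) and aminoacyl-tRNA synthetases 0.62 (17 of 23). Crabp1, a retinoic acid binding protein, stood at 1.85.

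Chromatin regulators had lower RPF than input values, with a median of -0.60 and 28 of 50 lower. Cytosolic ribosomal proteins had a median of -2.61, with 45 of 54 lower, and the mitochondrially encoded mRNAs a median of -6.26, with 7 of 7 measured members lower. For the ribosomal proteins the median share of unique subsequences was 60.3%, against 99.8% over all genes. Several genes with many input reads had almost no RPF reads. Gapdh had 154 and 159 input reads and 1 RPF read in each EV RPF library, and Actg1 had 183 and 174 input reads and 1 RPF read in each. Rpl9 had a log2 ratio of -6.59. For Gapdh and Actg1 the share of unique subsequences was 68.8% and 42.8%. Nhs had 3054 and 2641 input reads against 1 and 2 RPF reads, and Cbx8 6568 and 5618 against 7 and 11, although no other annotated exon overlaps either gene. No explanation of these values was tested, so they do not show how far these mRNAs are translated.

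The rank correlation of AGA frequency with the TE change is the first of 3 patterns weighed. With coding GC content and coding length held constant it was 0.00648, which is consistent with a dependence of TE on GC content or coding length, held constant together, rather than on AGA. The correlation of AGA frequency with the difference between the OE replicates was -0.143, larger in size than the 0.0443 between genotypes, so variation between libraries of 1 group may also produce it. That difference pairs RPF and input libraries by replicate number, although no pairing by number was seen. The other pairing was not run and may give another value. The rank of AGA among 61 codons was 10, on a bound set after that rank was seen (1 to 3 for, beyond 10 against), so this test decides nothing about decoding by the tRNA that METTL1 methylates.

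RPF of the mitochondrially encoded mRNAs rose in OE. A single library as the cause is argued against by a median change that was still 0.675 or more without any 1 of the 4 RPF libraries. Few RPF reads tested with the small spread of abundant input mRNAs would end the call with the 4 RPF libraries alone. The adjusted p of the list (camera) was 5.28e-06 there, although no single member passed and members had 4 to 95 RPF reads per library. That p rests on the preset correlation of 0.01, while the estimated correlation of this list was 0.1048 in the reported fit. The test on the 4 RPF libraries was not repeated with an estimated correlation, so few RPF reads stay open as a cause. A different recovery of mitochondrial against cytosolic footprints in the OE libraries cannot be told apart from a change in mitochondrial translation. The SD of the member changes was 1.22 times the median SE of a member, between the values set for either case. Members that rise by about the same factor would go with either cause, so a small spread could not have decided between them. The overexpression itself stays among the open explanations, as untested.

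TE of cytosolic ribosomal protein mRNAs was higher in OE, with a median of 0.27. Over the 7 members with at least 90% unique subsequences the median was 0.517, and all of them were above 0. Reads shared with pseudogenes and other copies as the whole cause would predict a median near 0 there. However, that share was computed over the longest annotated transcript and not over the coding sequence alone, so shared reads stay open as a cause. Short coding sequences are argued against by 10000 random lists matched on coding length, of which 2.5% had a median above 0.136. A single library is argued against by a median of 0.221 or more without any 1 of the 8 libraries. A translational response of these mRNAs to METTL1 and WDR4 may be tested in deeper libraries, since here it was found and weighed on the same data.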
